A study of Mus musculus with 4 samples.

How the data were processed

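Genomic DNA was taken from organoid cultures grown in vitro from mouse small intestine and from the spleen of the AKVL donor animal, with a column-based tissue kit, and libraries were made by standard Illumina procedures, per the labels' protocols. The animals were of a mixed strain background, per the labels. Of 4 labelled samples, the 3 organoid libraries AKVL, AKVPL and AKVPSL were used, 1 library for each genotype. The spleen library was not analysed here. Reads were aligned with GSNAP, and the builds GRCm38 and GRCh38 are both listed, per the submitters' processing notes. No version is given for GSNAP.

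The authors deposited a linear copy ratio, a ratio that is constant along each segment, and a whole-number copy number for consecutive windows of 50 kb, per the file headers and the window starts. There were 52685 windows on chromosomes 1 to 19 and X, and none on Y. The deposited ratio is centred near 1 by the authors, and a value of -1 marked 1663 windows (3.16%), the same ones in every library, which were left out. The remaining 51022 windows comprised 47846 on autosomes and 3176 on X. The program that made windows, segments and copy numbers, the library the ratio was taken against, and any correction for GC content or mappability are not given in the sources used here. A ratio corrected against a reference library and one corrected for GC content alone would carry different germline differences and different waves along the genome, so small regions that differ from 1 in every library were described as such.

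Sequencing was described as low coverage at 5X, per the labels. Read counts were not used here, so the depth of each library is unknown and no counting interval on a ratio was made. The noise of single windows, the SD from differences between neighbouring autosomal windows scaled from the median absolute deviation, was 0.0610 in AKVL, 0.0365 in AKVPL and 0.0399 in AKVPSL. Changes smaller than a 50 kb window, such as engineered exon deletions, cannot be seen in these values.

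A window was called gained or lost where its deposited copy number was above or below the most frequent autosomal copy number of the library, which was 2 in all 3. The ratio is relative, so ploidy was not measured, and copy numbers are read here on this baseline of 2. Shares of windows carry exact Clopper-Pearson 95% intervals. These treat windows as independent, although neighbouring windows share segments, and so they understate the spread. Chromosome medians are medians of the window ratio divided by the library's autosomal median, here called centred ratios. Their 95% intervals come from 1000 bootstrap draws of 5 Mb blocks. Both kinds of interval cover counting or variation along the genome within 1 library only, and say nothing about other cultures of the genotype. With 1 library per genotype there was no test between genotypes and no p-value. An autosome counted as gained as a whole where at least 80% of its windows were gained, and as partly altered where its longest altered segment reached 10 Mb.

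Overlap of altered windows between libraries was set beside the product of both shares and beside 100 circular shifts of one library's calls along the genome. Genes were placed from a RefSeq table of GRCm38.p6, whose last gene on each chromosome lay inside the last window of the files. A gene took the median call of the windows overlapping it, and a gene whose windows were evenly split between calls counted as unaltered. For 14 gene lists, the number of altered members was set beside 10000 random lists of the same size from 20452 autosomal protein-coding genes with a usable window, as a description of these libraries. The lists held 170 genes, of which 168 autosomal genes were measured.

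Lists, thresholds, the rule for naming genes and the comparisons of the report were fixed before the data were examined, except the ratios taken window by window against AKVPL. Most tests of explanations and some alternatives were chosen later, as stated where they are given. The rule named all engineered model genes, every change of at least 10 Mb, up to 30 list genes per library inside altered windows, taken by copy number and then by segment ratio, and the 5 altered segments under 10 Mb with the largest log2 segment ratio per library among those of at least 3 windows. Up to 5 protein-coding genes with an approved symbol were named in each segment. Genes on either side of the chromosome 8 boundary and other genes in the distal chromosome 9 segment, the desmosomal segment of chromosome 18, and Met, Dcc, Smad2, Axin2, Kif11, Mup1 and Amy2a5 were named after their values were seen. So were E2f1, Src, Hnf4a, Snai1 and Aurka on chromosome 2. Some genes that the rule selects, and the count of the engineered model gene list, are not reported here.

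Alternatives used other thresholds (1.2 and 0.8, or 1.3 and 0.7, on the centred segment ratio), 1 Mb bins, minimum segment lengths of 1 and 10 Mb, other centres, trimmed means and circular shifts. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data with gains and losses of known size placed on the 51022 real windows with the measured noise, and returned 24 of 24 known values.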

Results

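Low-coverage whole-genome sequencing was used to follow DNA copy number in mouse small-intestinal organoids, three-dimensional epithelial cultures, that carry an increasing number of colorectal cancer driver mutations. The organoid lines are named by letters that the labels do not spell out. In studies of this model they include Apc, Trp53, Smad4, a villin-driven recombinase and an Lgr5 reporter. AKVL was labelled adenoma, AKVPL carcinoma and AKVPSL metastatic adenocarcinoma. Each was represented by 1 library, so no difference between genotypes has a replicate check. The libraries were described as sequenced to 5X, and the noise of a single 50 kb window was 0.0610 in AKVL, 0.0365 in AKVPL and 0.0399 in AKVPSL on a ratio scale where 2 copies lie near 1.

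The first comparison asked how much of the genome departed from 2 copies as driver mutations were added. AKVPSL carried gains over large parts of its autosomes. AKVPL stayed close to the 2-copy baseline throughout, and AKVL did so apart from chromosome 19 and a smaller rise of chromosome 12. The ratio is relative and does not measure ploidy, so copy numbers are read here on a baseline of 2. In AKVPSL 12004 of 47846 autosomal windows (25.1%, 95% interval 24.7 to 25.5) had a copy number other than 2, against 500 windows in AKVL (1.05%, 0.956 to 1.14) and 86 in AKVPL (0.180%, 0.144 to 0.222). These intervals treat windows as independent and are too narrow. Leaving out 1 autosome moved the AKVPSL share to as low as 20.2% (chromosome 5) and as high as 27.3% (chromosome 1). Gains made up nearly all of the altered sequence in AKVPSL, with 11942 windows (597.1 Mb) gained and 62 windows (3.1 Mb) lost. Chromosomes 5, 6, 8, 15, 18 and 19 held 97.5% of its altered windows. The share did not climb step by step with the number of mutations, since AKVPL, with 1 more letter than AKVL, had the lowest share. In AKVL 349 of the 500 altered windows were on chromosome 19, and without that chromosome its share was 0.323%. With a segment ratio beyond 1.2 or 0.8 in place of the deposited copy number the shares were 2.36% in AKVL, 0.581% in AKVPL and 25.5% in AKVPSL.

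**Figure D1:**
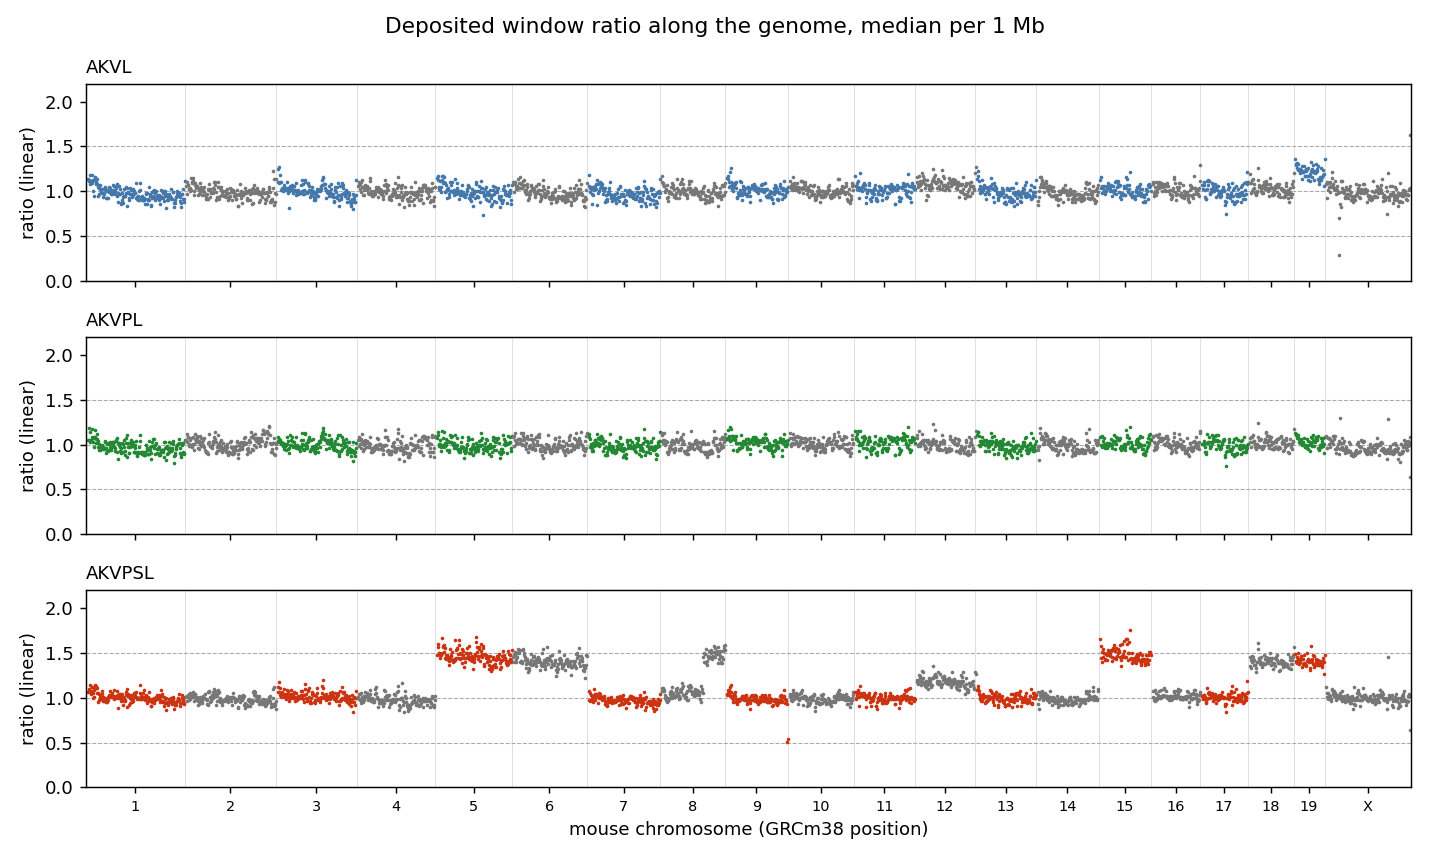
Deposited window ratio (linear, vertical axis) along mouse chromosomes 1 to 19 and X (horizontal axis), with 1 panel per library and 1 point per 1 Mb median, in alternating colours by chromosome. Dashed lines mark ratios of 0.5, 1 and 1.5. In AKVPSL chromosomes 5, 6, 15, 18 and 19 and distal chromosome 8 stand well above 1, and in AKVL chromosome 19 has a median of 1.22.

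Gained chromosomes were then examined one at a time. AKVPSL had 5 chromosomes gained from end to end, and neither AKVL nor AKVPL had any. Chromosome 15, which carries the Myc oncogene, had a centred ratio of 1.43 (1.41 to 1.44), and chromosome 5, which carries the cell cycle kinase gene Cdk6 and the intestinal transcription factor gene Cdx2, had 1.41 (1.40 to 1.43). Chromosomes 6, 19 and 18 had ratios of 1.36 (1.35 to 1.37), 1.36 (1.35 to 1.37) and 1.36 (1.35 to 1.37). Chromosome 6 holds Braf, and chromosome 18 holds Apc and Smad4. All windows of chromosomes 15, 18 and 19 were called at 3 or more copies, and so were 99.8% of those of chromosome 5 and 99.9% of those of chromosome 6. These chromosomes bear 1269 (chromosome 5), 1126 (chromosome 6), 776 (chromosome 15), 511 (chromosome 18) and 705 (chromosome 19) protein-coding genes. In AKVPL all 19 autosomes lay between 0.970 and 1.03. Because gains raise the autosomal median of AKVPSL to 1.03, ratios taken against its 2-copy windows were higher, at 1.47 for chromosome 15, 1.46 for chromosome 5 and 1.40 for each of chromosomes 6, 18 and 19.

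Chromosome 8 was gained in part in AKVPSL. The gain ran from 85000001 to 129350000 (GRCm38, 44.35 Mb, 887 windows), contained 420 protein-coding genes including the E-cadherin gene Cdh1 and Wwox, and had a centred ratio of 1.42 (1.41 to 1.45). The proximal part, from 3000001 to 85000000, had 1.02 (0.999 to 1.03), above the 0.942 to 0.984 of the 12 autosomes without a gain. Divided by AKVPL it was 1.02 (1.001 to 1.04), against at most 0.996 in those autosomes. Divided by AKVL it was 1.01 (0.996 to 1.02), against at most 0.998. The cause of this small rise was not tested. Distal chromosome 8 lay at 0.969 (0.946 to 0.991) in AKVL and 0.981 (0.945 to 1.02) in AKVPL. The boundary window fell in a gene-dense stretch. Rtbdn, Rnaseh2a, Prdx2 and the AP-1 subunit gene Junb lie on its proximal side, Hook2 (84988776 to 85003352) spans it, and Best2 and Get3 lie on its distal side. A window of 50 kb does not place the boundary within any 1 of these genes.

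A pair of chromosomes had ratios between those of 2 and 3 copies on the 2-copy baseline. Chromosome 19 of AKVL had a centred ratio of 1.22 (1.197 to 1.24), and 29.98% of its windows were called at 3 copies or more, the longest run being 6.5 Mb. Divided window by window by AKVPL, it was 1.18 (1.17 to 1.19), while 17 other autosomes ranged from 0.979 to 1.004. Chromosome 12 of AKVPSL had 1.14 (1.13 to 1.16), with 8.94% of its windows called gained, against 0.942 to 0.984 in the 12 autosomes without a gain. Chromosome 12 was also the second highest autosome of AKVL, at 1.07 (1.05 to 1.08). In AKVPL, chromosomes 12 and 19 had 0.996 (0.979 to 1.01) and 1.03 (1.01 to 1.06). By the rule of 80% of windows AKVL had no gained chromosome, and by a chromosome median above 1.2 it had 1, chromosome 19.

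**Figure D2:**
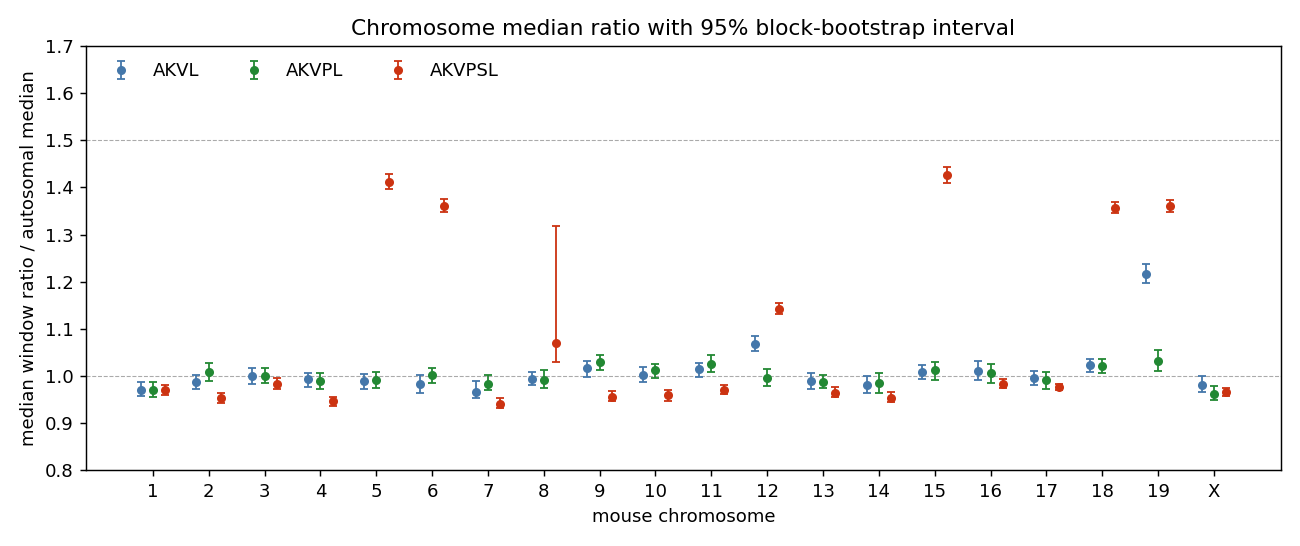
Median window ratio of each chromosome divided by the library's autosomal median (vertical axis, linear) for chromosomes 1 to 19 and X (horizontal axis). Points are the 3 libraries and bars are 95% block-bootstrap intervals. Chromosome 8 of AKVPSL is a mixture of a proximal part at 1.02 and a gained distal part, which widens its interval to 1.03 to 1.32. Chromosome 12 of AKVPSL (1.14) and chromosome 19 of AKVL (1.22) lie between the other chromosomes and the gained ones.

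Among segments under 10 Mb with at least 3 windows, 1 loss was called in AKVPSL and not in the other libraries. It covered 1.9 Mb of distal chromosome 9, from 122600001 to 124500000, with a ratio of 0.511 (SD 0.0512 over 38 windows), and ran to the last usable window of the chromosome. The same windows had ratios of 1.02 in AKVL and 1.02 in AKVPL, and the 5 Mb before them had 0.971 in AKVPSL. The segment held 38 protein-coding genes, beginning with Topaz1, Tcaim, Zfp445, Zkscan7 and Zfp660. It also held the chemokine receptor genes Ccr1, Ccr2, Ccr3, Ccr9 and Cxcr6, the mitotic kinesin gene Kif15, Limd1, Lztfl1 and Lars2, which encodes the mitochondrial leucyl-tRNA synthetase.

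**Figure D3:**
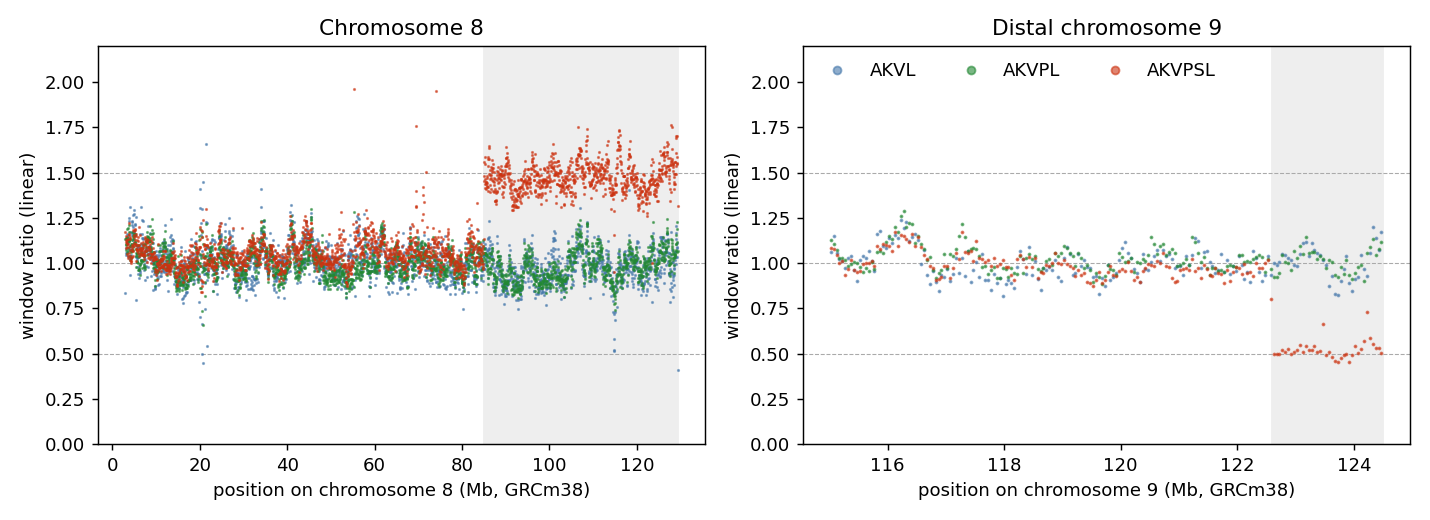
Window ratio (linear, vertical axis) by position in Mb (horizontal axis) on chromosome 8 (left) and distal chromosome 9 (right), with 1 point per 50 kb window and a colour per library. Grey marks the segments called gained or lost in AKVPSL. AKVPSL steps up at 85000001 to a ratio of 1.47 on chromosome 8 (1.42 when centred) and down to 0.511 at the end of chromosome 9. AKVL and AKVPL stay near 1 in both.

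Other short segments were found in more than 1 library. A 0.4 Mb stretch of chromosome 1 inside Pard3b, a cell polarity gene (62150001 to 62550000, 8 windows), was called at 1 copy in all 3 libraries, with ratios of 0.739 (SD 0.0379 over windows) in AKVL, 0.489 (SD 0.0391) in AKVPL and 0.501 (SD 0.0367) in AKVPSL. A 0.15 Mb stretch in Auts2 on chromosome 5 (131650001 to 131800000) had 0.612, 0.466 and 0.614 in the same order, and was called at 1 copy in AKVPL and AKVPSL even though the rest of chromosome 5 was gained in AKVPSL. On chromosome 18, a stretch of 1.35 Mb from 19700001 that was singled out after its values were seen and holds the desmosomal cadherin genes Dsc1, Dsc2, Dsc3, Dsg1a and Dsg1c had ratios of 1.26, 1.24 and 1.61. The end of chromosome X with Mid1 and Asmt (169950001 to 170900000, 6 usable windows) had 1.49 in AKVL, 0.621 in AKVPL and 0.616 in AKVPSL. The remaining named segments fell in multigene families or in sequence without a named gene. AKVL had a ratio of 0 over the vomeronasal receptor genes Vmn1r148, Vmn1r149, Vmn1r151, Vmn1r152 and Vmn1r255 on chromosome 7 (22400001 to 22700000), 0.693 over Pramel38 to Pramel41 on chromosome 5 (94150001 to 94450000), 0.675 over Cldn34c2 and Cldn34c3 on X (123300001 to 123850000) and 0.558 at 28000001 to 29850000 on X. AKVPL had 0.651 over Pramel45 and Pramel46 (chromosome 5, 94950001 to 95300000) and 0.374 at 5450001 to 5750000 of chromosome 14. AKVPSL had 1.65 at 29900001 to 30150000 of X, where AKVL had 1.72 and AKVPL 1.19. In total 24 segments of at least 3 windows and under 10 Mb were altered in AKVL (15 gains, 9 losses), 10 in AKVPL (4 gains, 6 losses) and 20 in AKVPSL (16 gains, 4 losses). Chromosome 19 held 9 of the gains of AKVL and chromosome 12 held 9 of those of AKVPSL, the chromosomes with ratios between those of 2 and 3 copies.

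The overlap between libraries addressed whether altered windows recur across genotypes. AKVL and AKVPL shared 34 gained windows, where independent sets would share 0.538 and the highest of 100 circular shifts shared 10. They shared 13 lost windows, where independent sets would share 0.0328 and the highest shift shared 0. AKVPL and AKVPSL shared 14 lost windows against 0.0363 for independent sets and 4 in the highest shift. AKVL and AKVPSL shared 389 gained windows against 110.8, but the highest of the shifts reached 399. For AKVPL and AKVPSL the 39 shared gained windows compare with 14.5 for independent sets and 41 in the highest shift. AKVL and AKVPSL shared 9 lost windows against 0.0726 and 0 in the highest shift. Windows of 1 segment are not independent, so window counts overstate the number of shared segments. Of the 34 gained windows shared by AKVL and AKVPL, 25 are 1 segment on chromosome 18. Of the 14 lost windows shared by AKVPL and AKVPSL, 8 are the stretch in Pard3b. In all 3 libraries 33 windows were gained, 25 of them on chromosome 18, which is gained whole in AKVPSL, and 9 were lost, 8 of them the stretch in Pard3b. Shared gained windows as a percent of the smaller set were 58.6 for AKVL with AKVPL, 87.6 for AKVL with AKVPSL and 67.2 for AKVPL with AKVPSL, and 20, 12.9 and 36.7 with chromosomes 5, 6, 8, 15, 18 and 19 left out, a choice made after seeing the data.

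Genes linked to the design of this model were read next, with Vil1 included only because the recombinase is villin-driven. Trp53, Lgr5 and Vil1 were at 2 copies in every library, and Apc and Smad4 were at 2 copies in AKVL and AKVPL and at 3 in AKVPSL. Apc (chromosome 18, 34220297 to 34322190), the Wnt pathway tumour suppressor, had a window ratio of 0.952 in AKVL, 1.04 in AKVPL and 1.35 in AKVPSL. Smad4 (chromosome 18, 73634790 to 73703791), the common mediator of TGF-beta signalling, had 1.03, 1.06 and 1.35. Trp53 (chromosome 11, 69580348 to 69591873), which encodes p53, had 1.07, 1.001 and 0.969. The stem cell receptor gene Lgr5 (chromosome 10, 115450314 to 115587780) had 1.08, 1.08 and 1.04, and Vil1 (chromosome 1, 74409384 to 74435560), which encodes villin of the intestinal brush border, had 1.04, 0.980 and 1.01. These genes span 1 to 3 windows, and deletions smaller than a window were not detectable at this resolution.

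Gene groups fixed beforehand were placed on the gains of AKVPSL, where 46 of 168 measured list genes were gained and 0 were lost as a whole. Mup1, a major urinary protein gene on chromosome 4, had 1 of its 2 windows called at 1 copy in AKVPSL (ratio 0.480) and the other at 2 (1.03), and such even splits counted as unaltered. In AKVL and AKVPL 0 list genes were altered. For comparison, 23.4% of 20452 protein-coding genes were gained in AKVPSL, 1.89% in AKVL and 0.117% in AKVPL. With the segment ratio threshold of 1.2, AKVL had 4 altered list genes, namely Axin2, Myc, Ide and Kif11, and AKVPL had 2, Axin2 and Snai1. The amylase gene Amy2a5 was left out because 1 of its 2 windows passed (1.86 in AKVL, and 1.61 in AKVPSL) and the other did not.

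Of 19 RAS-MAPK and receptor genes, 6 were gained, among them the epidermal growth factor receptor ligand genes Areg (ratio 1.62) and Ereg (1.58) and the kinase gene Braf (1.32), and 28.7% of random lists had as many. Of 20 Wnt and stem cell genes, 5 were gained, including Myc (1.60), the Wnt agonist gene Rspo2 (1.41) and the co-receptor gene Lrp6 (1.40), and 53.6% of random lists had as many. Gene ratios here are not centred. Myc covered 1 window and had a segment ratio of 1.43, against an uncentred 1.47 for the whole of chromosome 15. It was at 1.16 in AKVL and 1.05 in AKVPL, both called at 2 copies. In the TGF-beta and BMP list 4 of 15 were gained (48.8% of random lists had as many), among them the receptor gene Acvr1b (1.54). Acvr1b was at 1.13 in AKVL and 1.15 in AKVPL, both called at 2 copies. In the cell cycle list 4 of 17 were gained (59.7%), with Cdk6 at 1.42 and the spindle checkpoint gene Mad2l1 at 1.40. The p53 and DNA damage list had 2 of 14 gained (88.0%), with the homologous recombination gene Brca2 at 1.42, and the mismatch repair and polymerase list had 2 of 7 (52.0%), with Pms2 at 1.41. The PI3K-mTOR list had 1 of 11 gained (95.2%). Intestinal differentiation genes were gained in 5 of 14 cases (22.1%), with the homeobox genes Cdx2 at 1.42 and Cdx1 at 1.40, the secretory lineage factor gene Atoh1 at 1.31 and the fatty acid binding protein gene Fabp1 at 1.34. The adhesion and invasion list had 3 of 12 gained (56.5%), with Cdh1 at 1.60 and Zeb1, a repressor of Cdh1, at 1.33.

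Lists drawn from human colorectal cancer were both represented among the gains. Of 15 genes recurrently gained in human tumours, 6 were gained in AKVPSL, and 12.2% of random lists had as many. They were Cdk8 (1.40), Cdx2 (1.42), Flt3 (1.42), Met, Myc (1.60 in its 1 window) and Gata6 (1.38). Of 14 genes recurrently lost in human tumours, 7 were also gained in AKVPSL, including Wwox (1.40), Apc, Dcc, Smad4 and Smad2, and 2.56% of random lists had as many. Apc, Dcc, Smad4 and Smad2 lie together on chromosome 18, so members of this list are not independent. Apc and Smad4 are also linked to the design of this model. Engineered changes smaller than a window cannot be seen, so a gain does not show that the extra copy works. With circular shifts of the calls, which keep neighbouring genes together, 12.4% of shifts had as many for the second list and 28.9% for the first. Among 10 antigen receptor genes, included as markers of lymphoid DNA, 4 were gained (19.9% of random lists had as many), all on the gained chromosome 6, with Igkc at 1.40 and Trbc1 at 1.43. Of 11 strain-variable genes 4 were gained (25.4%), Klra8 (1.41), Klra1 (1.46), Cyp2d22 (1.33) and Ide (1.35), and each lies on a gained chromosome. Off the gained chromosomes, Amy2a5 (chromosome 3) had a median ratio of 1.42 in AKVL, 1.18 in AKVPL and 1.3004 in AKVPSL, and Mup1 had 0.781, 0.873 and 0.756.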

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

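The comparisons of opposite calls in this part were chosen after the calls were seen, and none of these differences was tested, since each genotype has 1 library. At the end of chromosome X with Mid1 and Asmt, AKVL was called gained, with a ratio of 1.49, and both AKVPL (0.621) and AKVPSL (0.616) were called lost. Of the 19 windows of the stretch 13 (68.4%) had no value, against 7.16% over chromosome X. AKVL was the highest library in 6 of the 6 windows with a value. Effects of mapping or of the mixed strain background there were not tested. The stretch of chromosome 5 with Pramel38 to Pramel41 (94150001 to 94450000) was called lost in AKVL (0.693) and gained in AKVPSL (1.75), and lies on a chromosome gained as a whole in AKVPSL. The vomeronasal receptor genes on chromosome 7 (22400001 to 22550000) were called lost in AKVL, with a ratio of 0, and gained in AKVPSL (1.29), with 1.13 in AKVPL. An overlapping stretch with Vmn1r152 and Vmn1r255 (22500001 to 22750000) was called lost in AKVPL (0.737), where AKVPSL had 0.944. Pramel45 and Pramel46 (chromosome 5, 94950001 to 95300000) were called lost in AKVPL (0.651) and gained in AKVPSL (1.31), with 0.7705 in AKVL. The AKVPSL value lies below the uncentred 1.45 of its chromosome 5 as a whole. The rest of chromosome X had a centred median of 0.980 in AKVL, 0.963 in AKVPL and 0.966 in AKVPSL.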

How the results depend on the processing

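Alternatives that centre on 2-copy windows for altered shares, divide by AKVPL, or leave out chromosomes 5, 6, 8, 15, 18 and 19 were chosen after seeing the data, and the rest before. No called gain or loss changed direction, 86 values stayed within their interval, noise or 1.5-fold range, and 74 moved out of it. The intervals of window shares are narrow because they treat windows as independent. Ratios of genes called at 2 copies crossed 1 for Vil1 in all 3 libraries, Apc in AKVL and Smad4 in AKVPL. The cause was not tested except where the alternative's construction gives it. The order of altered shares, AKVPSL above AKVL above AKVPL, held except at a 10 Mb minimum. In AKVL the share was 2.36% with segment ratios beyond 1.2 or 0.8 (also 2.36% centred on 2-copy windows), 0.481% beyond 1.3 or 0.7, 2.21% in 1 Mb bins, 0.721% with segments of at least 1 Mb, 0% at 10 Mb and 0.323% without chromosome 19. In AKVPL these were 0.581% (also 0.581%), 0.107%, 0.293%, 0.0523% and 0%, with 0.0920% without windows altered in all libraries and 0.132% without chromosome 18. In AKVPSL they were 25.5% (25.9%), 23.6% and, at 10 Mb, 24.4%, with 20.2% without chromosome 5 and 27.3% without chromosome 1. Centred on 2-copy windows, AKVPSL chromosomes 5, 6, 12, 15, 18 and 19 had 1.46, 1.40, 1.18, 1.47, 1.40 and 1.40. Divided by AKVPL, chromosomes 18 and 19 of AKVPSL had 1.33 and 1.33 and chromosome 19 of AKVL had 1.18, and by segment ratios chromosome 19 of AKVPSL had 1.35. By chromosome medians AKVL had 1 whole-chromosome gain. The gained windows shared, as a percent of the smaller set, were 58.6 for AKVL with AKVPL, 87.6 for AKVL with AKVPSL and 67.2 for AKVPL with AKVPSL. They became 43.8, 17.1 and 43.8 by reciprocal overlap of segments, 100 for each at a 1 Mb minimum, 36.9, 84.1 and 35.6 by segment ratios, and 20, 12.9 and 36.7 with chromosomes 5, 6, 8, 15, 18 and 19 left out, so AKVL with AKVPSL went from the highest of the 3 pairs to the lowest by reciprocal overlap and with those chromosomes left out. At the 1 Mb minimum AKVPL kept gains only in a segment of 25 windows on chromosome 18. AKVL kept gains only on chromosomes 18 and 19. Both chromosomes are gained whole in AKVPSL, so the values of 100 with AKVPSL were fixed in advance. Shared losses of AKVL with AKVPL went from 46.4 to 75.5 by segment ratios and 68.4 with those chromosomes left out, and a 1 Mb minimum left no losses to share in any pair. With 1 Mb on each side of the gene, ratios were 0.974 for Vil1 and 1.05 for Apc in AKVL, 1.09 for Trp53 and 1.01 for Smad4 in AKVPL, and 1.41 for Apc in AKVPSL. By segment ratio they were 1.01 for Lgr5 in AKVL, 1.03 for Vil1, 1.07 for Trp53 and 0.989 for Smad4 in AKVPL, and 1.40 for Apc in AKVPSL. With circular shifts, the percent with as many altered genes in AKVPSL was 55.6 for Wnt, 54.7 for TGF-beta and BMP, 34.3 for RAS-MAPK, 99.5 for PI3K-mTOR, 89.8 for p53, 56.5 for mismatch repair, 63.1 for cell cycle, 28.9 for genes gained and 12.4 for genes lost in human tumours, 60.5 for adhesion, 25.4 for differentiation, 33.9 for antigen receptor and 28.5 for strain-variable genes. By segment ratios it was 53.1 for mismatch repair, 3.17 for genes lost in human tumours and 23.1 for differentiation, and 4 list genes in AKVL and 2 in AKVPL were altered. No paired analysis was possible because each genotype has 1 library, and for that reason no library could be left out of a group. Depth is unknown, and window noise was highest in AKVL (0.0610), where calls of 1 or 2 windows are least certain.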

Other observations

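The tests of intermediate and unequal ratios reported here were chosen after those ratios were seen, except the corrections for gene density. Small differences along chromosomes recurred across libraries. A reference library or correction common to them would also give this, and neither is known here. Over 31979 windows of autosomes without a gain, window ratios correlated with r of 0.669 between AKVL and AKVPL, 0.586 between AKVL and AKVPSL and 0.615 between AKVPL and AKVPSL, across windows that are not independent. Areg and Ereg, neighbours on chromosome 5, had ratios of 1.19 and 1.22 in AKVL and 1.17 and 1.17 in AKVPL, where both are called at 2 copies. Cdh1 had 1.16 and 1.16, and Wwox, a long gene also on distal chromosome 8, had 0.842 and 0.851. Chromosome X had centred medians of 0.981 in AKVL, 0.963 in AKVPL and 0.966 in AKVPSL.

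Chromosome 19 of AKVL lay between the ratios of 2 and 3 copies on the 2-copy baseline. Waves shared by the libraries do not account for it, since its ratio to AKVPL was 1.18 (1.17 to 1.19) against 1.07 for chromosome 12 and at most 1.004 for the 17 other autosomes. Carry-over of AKVPSL DNA would need a mixture of 54.0% and would put chromosomes 5, 6, 15 and 18 at 1.21 relative to AKVPL, where their median was 0.993. A linear correction for gene density left it at 1.21 but changed the SD over those 17 autosomes by 0.629% only and so tested little. A GC effect alike across the genome, with gene density as stand-in, would raise like bins elsewhere. All 13 bins of 5 Mb (median 1.18 relative to AKVPL, lowest 1.15) lay above the highest (1.08) of 374 such bins. Gene density followed the AKVL ratio only weakly, with r of 0.123 across windows of those 17 autosomes. Bins of like gene density need not be alike in GC content, so this comparison cannot decide on a GC effect. An extra chromosome 19 in part of the AKVL cells (43.5% if the other cells have 2 copies) is a hypothesis that needs an even level along the chromosome. The SD of its 13 bins was 0.0161 against a scaled median of 0.0295 within other autosomes, but a bias of the whole chromosome would be as even. Shares of cells given here and below rest on the 2-copy baseline. Ploidy was not measured, and another baseline would give other shares.

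Chromosome 12 of AKVPSL showed the same kind of intermediate ratio. It remained at 1.15 (1.13 to 1.16) relative to AKVPL, against a highest value of 0.996 in 12 unchanged autosomes, and at 1.07 (1.06 to 1.08) relative to AKVL, against a highest value of 0.998. Dilution of the culture by 2-copy DNA would lower all gains alike, but its centred ratio of 1.14 (1.13 to 1.16) was below the lowest bound of the whole-chromosome gains, 1.35. The correction for gene density left it at 1.14, changed the SD over the 12 autosomes by 3.18% and tested little. Of its 24 bins of 5 Mb (median 1.14 relative to AKVPL) 23 lay above the highest (1.09) of 269 bins of like gene density and the lowest, 1.06, did not. Gene density followed the AKVPSL ratio only weakly, with r of -0.115 across windows of the 12 autosomes. The comparison of bins therefore cannot decide on a GC effect here either. Chromosome 12 was also raised in AKVL, at 1.07 (1.06 to 1.08) relative to AKVPL, so a bias on this chromosome that AKVPL lacks stays open for part of the excess, and an extra chromosome 12 in part of the cells (35.7% if the others have 2 copies) may contribute, as the SD of its bins, 0.0399, was no larger than the scaled median of 0.0412 within other autosomes, but a bias of the whole chromosome would give the same.

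Whether the gains of AKVPSL lie at 1 level, as a single share of cells carrying every gain would give, was left open. Centred ratios of the 6 gained regions had a range of 0.0707, which exceeds the 0.0588 found by scaling the range of unchanged autosomes to the gained ratio by less than the SD of those autosomes, 0.0140. Relative to AKVPL the range was 0.128 against 0.0837 (SD 0.0194), or 0.121 against 0.0844 without chromosome 19, and relative to AKVL, without chromosome 19, it was 0.147 against 0.0762 (SD 0.0154). The excess was thus larger than the SD after division only, which does not decide the question. Division also carries over unevenness of the denominator. AKVPL had centred ratios of 0.981 for distal chromosome 8, 1.02 for chromosome 18 and 1.03 for chromosome 19. If each gain is 1 extra copy, the ratios to 2-copy windows would correspond to between 79.8% of cells for chromosome 18 and 94.4% for chromosome 15, and the loss on chromosome 9 to 97.5%.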
